A study of Homo sapiens with 24 samples.

How the data were processed

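Per the labels, total RNA of IMR-32 and SK-N-AS cells was extracted with TRIzol, arrays were used only for RNA above a set integrity number, and RNA was amplified, labelled with Cy3 and hybridized to one-colour oligonucleotide arrays. The authors name limma, with no version, for the processing. The deposited values are linear fluorescence intensities, from 1.32 to 309395 units, for 44708 features on 24 arrays. They had been brought to a common distribution by the authors: arrays differ by at most 0.0723% at any rank, and every array has a median of 114 units. The comparisons had been planned for log2 values, so log2 of the deposited intensity was taken, with no offset. No background or detection flags were used, so values near the lowest intensity cannot be told from background, and folds against such a level depend on it. The table holds no counts, so the depth per array is unknown.

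Probes were paired with genes through the platform's annotation: 27942 probes have 1 gene symbol and 16766 have none. Of 17370 symbols, 14295 are current, 2937 were updated through a synonym, 129 with more than 1 possible update were kept as they are, and 9 were not found and kept. This gave 17199 genes, 7572 of them with 2 or more probes, each represented by the probe with the highest mean over all arrays. No sample column was left out, and features without a symbol were set aside from the comparisons of genes.

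Groups were taken from the labels, with 6 arrays in each of the 4 groups. Because each group has 1 array per hour, the hours stand in for replicates. The HOXC9 against GFP comparisons used 20 arrays (6 to 96 h) of both lines in a single limma fit with a block for each line and hour and a transgene effect per line, which leaves 8 residual degrees of freedom. The difference of these effects, SK-N-AS minus IMR-32, was tested in the same fit. Trends used 24 arrays and the HOXC9 minus GFP difference against log2(1 + h/6), with line-by-hour blocks. The GFP arrays were compared between lines with hour as a block, and over time with 1 slope for both lines. Tests were two-sided moderated tests by eBayes, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The 0 h arrays were described without a test. Same-hour arrays of a line were checked for sharing more than their hour: their correlation after group means were taken out was 0.159 to 0.408 in IMR-32 and -0.074 to 0.169 in SK-N-AS, highest at the same hour for 6 of 12 arrays.

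Before the data were examined, 33 gene lists, the comparisons, the alternatives and the rule for named genes were fixed. Lists were tested with camera at an inter-gene correlation of 0.01, and again with the correlation estimated per list, and adjusted over the 33 lists within a comparison. HOXC9 itself was left out of every list. In each line the rule named the 10 largest rises and 10 largest falls among called genes with the same sign at each of 5 hours and a mean in the higher group above the 40th percentile of genes (log2 7.28). In the other comparisons it took the 5 largest in each direction, or the smallest p where none passed, among genes whose mean over all arrays of the comparison lay above that level. Genes that are bright in a single group can miss it. For the differences between lines the same sign at each hour was also asked for. It added up to 4 members per list with the smallest p, and those of the genes fixed beforehand that are in the analysed values. Not every gene the rule names is described. For the difference between lines of the GFP arrays, 3 of the 5 genes furthest toward IMR-32 are given.

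Alternatives, whose effects the closing section gives, were other scalings, leaving out dim genes, other choices of probe, other eBayes settings, array weights, leaving out each hour, no block, other hours, the difference at 0 h subtracted, each line's arrays alone and other codings of the hour. Chosen after seeing the data were offsets of 16 and 50 units, scalings over the tested genes alone, SK-N-AS without or with only 6, 12 and 24 h, and the difference between lines with the arms of SK-N-AS turned. Neighbour order came from the GRCh38.p14 annotation, used for names and order alone, with windows of 51 genes. The fits were tested on simulated data with normal noise of each gene's residual spread and 200 changed genes: the HOXC9 against GFP fit recovered 74.6% of 2-fold changes in IMR-32 and 65.7% in SK-N-AS, and the trend fits recovered 0% and 2.99% of 2-fold and 43.9% and 50.0% of 4-fold changes. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.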

Results

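Gene expression was measured in total RNA from 2 human neuroblastoma cell lines, IMR-32, which carries an amplified MYCN oncogene, and SK-N-AS. Cultures of each line were labelled by transgene, HOXC9 or the control GFP (green fluorescent protein), and by hour, from 0 h through 6, 12, 24 and 48 h to 96 h. HOXC9 is a homeobox transcription factor encoded in the HOXC cluster. Each line, transgene and hour had 1 one-colour array, so each of the 4 groups held 6 arrays and no hour was replicated. Every array had a median intensity of 114 units over 44708 features, with quartiles of 9.68 and 1065 units, and 17199 named genes were tested. All levels are log2 intensities, and the number of arrays limits the precision of every value. The labels do not say whether 0 h precedes the onset of transgene expression.

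The HOXC9 probe was much brighter in the HOXC9 than in the GFP arrays of IMR-32 and slightly dimmer in the arrays labelled HOXC9 of SK-N-AS. In IMR-32, HOXC9 averaged 10.02 ± 0.19 (SD, n = 5) in the HOXC9 arrays at 6 to 96 h and 5.94 ± 0.26 in the GFP arrays. The difference was 4.08 ± 0.13 (SE; adjusted p = 1.77e-08), HOXC9 was higher at each of the 5 hours, and the difference at 0 h was 4.16. In SK-N-AS, HOXC9 averaged 11.71 ± 0.06 in the arrays labelled HOXC9 and 12.28 ± 0.17 in the GFP arrays, so the probe went against the label at each of the 5 hours. That HOXC9 difference was -0.57 ± 0.13 (adjusted p = 0.00721), against -0.54 at 0 h. With the SK-N-AS arrays of 6, 12 and 24 h left out, HOXC9 in SK-N-AS differed by -0.52 (adjusted p = 0.167). Among the GFP arrays, HOXC9 was 6.33 ± 0.13 higher in SK-N-AS than in IMR-32. The labels do not say whether this probe lies in the part of the transcript that the transgene carries.

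Genes beside HOXC9 differed as well. In IMR-32, 4 of the 8 other measured genes of the HOXC cluster were higher in the HOXC9 arrays and 0 were lower, with the same counts adjusted over the list alone. HOXC8 was higher by 5.27 ± 0.30 (adjusted p = 9.77e-07), HOXC5 by 2.55 ± 0.31, HOXC10 by 2.07 ± 0.30 and HOXC6 by 1.01 ± 0.17. HOXC10 differed by 2.74 at 6, 12 and 24 h but by 0.83 at 0 h and 1.07 at 48 and 96 h. The other HOXC10 probe stood at 0.46 in both arms of IMR-32, near the lowest intensity of the data, and tells nothing either way. At 0 h HOXC6 was lower in the HOXC9 array, 2.00 against 2.40. These are dim probes: HOXC8, the brightest of them, averaged 6.05 ± 0.40 (SD, n = 6) in the IMR-32 HOXC9 arrays and 0.75 ± 0.11 in the GFP arrays. HOXC5 averaged 3.86 against 1.36, HOXC10 3.89 against 2.03 and HOXC6 2.17 against 1.40. The differences of HOXC5, HOXC10 and HOXC6 therefore depend on the lowest intensities. In SK-N-AS, HOXC6 was higher by 0.64 ± 0.17, and HOXC8 and HOXC10 were lower, at -1.39 ± 0.30 and -1.27 ± 0.30, in the arrays labelled HOXC9. The other HOXC8 probe gave 4.96 ± 0.20 in IMR-32 and 0.46 ± 0.20 (adjusted p = 0.0949) in SK-N-AS. The HOXC8 probes part in SK-N-AS at 6, 12 and 24 h, with mean differences of -2.05 and 0.92, and at 48 and 96 h these were -0.38 and -0.23.

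**Figure D1:**
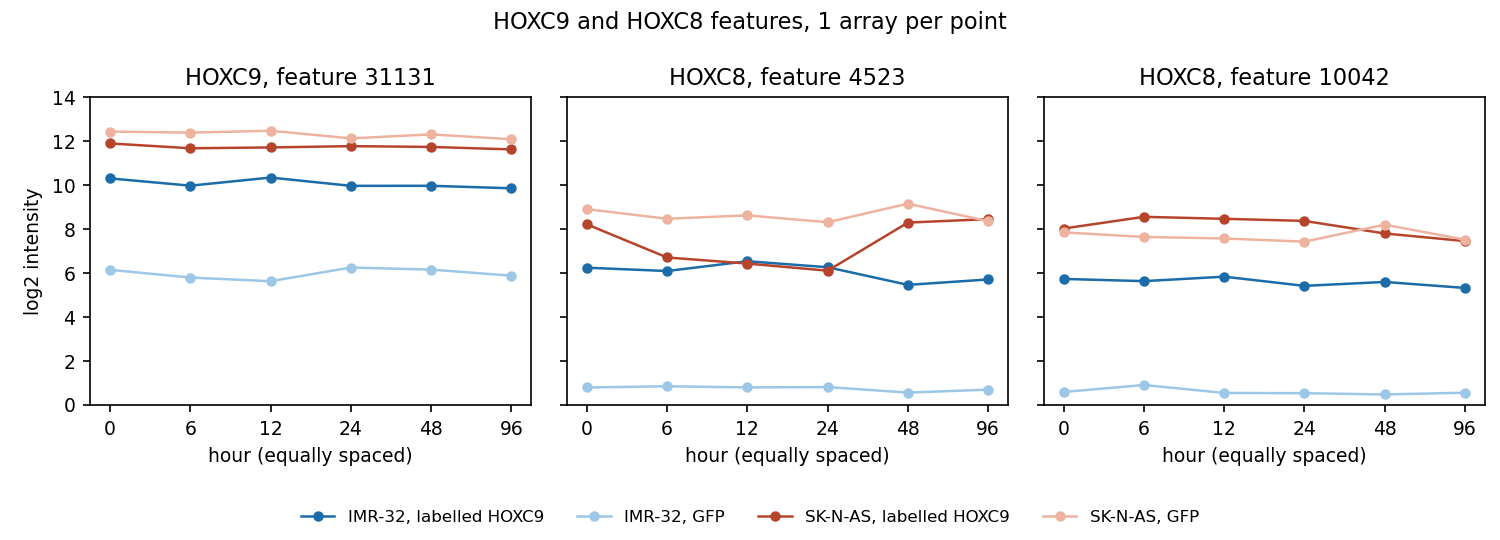
Log2 intensity (vertical axis) of the HOXC9 probe and both HOXC8 probes against hour (horizontal axis) in the HOXC9 and GFP arrays of IMR-32 and SK-N-AS, 1 array per point. The HOXC9 lines of IMR-32 lie apart at 0 h already, by 4.16, and the SK-N-AS lines lie in the opposite order, by -0.54.

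In IMR-32, the comparison asks which genes differed between HOXC9 and GFP cultures over 6 to 96 h. EPHA5, an ephrin receptor, was higher by 8.76 ± 0.38 (adjusted p = 1.38e-07), from 0.78 ± 0.80 (SD, n = 5) in the GFP arrays to 9.54 ± 0.07. NEUROD1, a neurogenic transcription factor, was higher by 6.78 ± 0.17, RELN, the secreted guidance protein reelin, by 6.54 ± 0.13, and VEGFD, a lymphangiogenic growth factor, by 6.71 ± 0.28. The interferon-induced IFI44 was higher by 6.64 ± 0.17 and the p53-induced RPRM by 7.04 ± 0.47. The other genes with the largest rises were SLC24A3, PPP1R17, TSPYL5 and ZNF671, at 6.51 to 7.75. FLI1, an ETS transcription factor, was lower, at -6.64 ± 0.22 (adjusted p = 2.14e-08), as were the cancer-testis antigen gene GAGE12F at -5.62 ± 0.18, the growth factor FGF10 at -4.98 ± 0.36 and the transcription factor SOX9 at -3.07 ± 0.15. TMEM204, TES, CGNL1, LIX1, SCGN and CRYGD were lower by between -5.47 and -3.13.

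The series names the intrinsic pathway of apoptosis, which runs through the mitochondria. In IMR-32, 2 of the 22 measured pro-apoptotic members of this pathway were higher and 2 lower in the HOXC9 arrays, with the same counts adjusted over the list alone. Cytochrome c, CYCS, was higher by 0.92 ± 0.16 (adjusted p = 0.00254) and the BH3-only gene HRK by 0.92 ± 0.20, while the BH3-only gene BCL2L11 was lower, at -0.62 ± 0.11, and ENDOG at -0.50 ± 0.14. Among 12 anti-apoptotic genes, BIRC3 was higher by 1.70 ± 0.29 and BCL2 lower, at -0.55 ± 0.10 (adjusted p = 0.00261), again with 1 and 1 adjusted over the list alone. BAX differed by -0.04 ± 0.10, BBC3 by -0.47 ± 0.27, PMAIP1 by 0.24 ± 0.17, BCL2L1 by -0.06 ± 0.10 and CASP9 by 0.07 ± 0.09, none past the threshold (smallest adjusted p = 0.237). Of 18 death receptor genes, 5 were higher and 0 lower (5 and 0 adjusted over the list alone), among them TNFRSF1A at 1.27 ± 0.17 and TNFRSF10B at 0.36 ± 0.07. Of 28 p53 targets, 3 were higher and 2 lower, with the same counts adjusted over the list alone, and TIGAR at -3.21 ± 0.32 and GDF15 at -2.03 ± 0.42 were the lower ones.

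Cell cycle genes of IMR-32 differed little. KIF2C was higher by 0.54 ± 0.12 and CDC20 by 0.36 ± 0.09, the 2 of 28 genes of G2/M and mitosis past the threshold (2 adjusted over the list alone). PCNA at 0.28 ± 0.07 and CDC25A at 0.22 ± 0.07 were the 2 of 31 genes of G1/S and DNA replication (0 adjusted over the list alone). The cyclin CCND1 was higher by 0.27 ± 0.08 (adjusted p = 0.0368), a call that leaving out the arrays of 6, 24, 48 or 96 h ended (CCND1 in IMR-32 HOXC9 vs GFP, adjusted p = 0.0834 to 0.125). This holds for its brightest probe alone, since the other CCND1 probes stood at -0.06, -0.04 and -0.07. The proliferation marker MKI67, at -0.20 ± 0.11, CDKN1A, at 0.32 ± 0.17, and MYCN, at -0.58 ± 0.24 (adjusted p = 0.101), did not pass on their brightest probes. Another MYCN probe was lower, at -0.55 ± 0.11 (adjusted p = 0.00504), and the remaining MYCN probes stood at -0.65 ± 0.28 and 0.02 ± 0.24. Among 7 CDK inhibitors, CDKN2A was higher by 0.72 ± 0.15, CDKN1B by 0.78 ± 0.16 and CDKN1C lower, at -0.70 ± 0.20 (3 higher and 2 lower adjusted over the list alone).

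Identity genes of IMR-32 moved both ways. Of 22 noradrenergic genes, 4 were higher and 3 lower (4 and 5 adjusted over the list alone). Neuropeptide Y, NPY, was higher by 1.48 ± 0.13 and the receptor RET by 1.60 ± 0.19, and the monoamine oxidase MAOA was lower, at -1.59 ± 0.17. Of 21 mesenchymal genes, 4 were higher, such as VIM at 1.17 ± 0.07, and 7 lower, such as LMNA at -0.82 ± 0.12 (5 and 7 adjusted over the list alone). Of 28 genes of neuronal differentiation, 4 were higher and 1 lower (3 and 0 adjusted over the list alone). The neuroblast microtubule protein DCX stood at 3.33 ± 0.20 and the neurotrophin receptor NGFR at 1.71 ± 0.26. In signalling lists, CYP26A1, a retinoic acid hydroxylase, was higher by 4.66 ± 0.34, the YAP and TGF-beta target CCN1 by 4.04 ± 0.34 and the Notch ligand-like DLK1 by 3.31 ± 0.19, while HES1 was lower, at -3.23 ± 0.24, DKK1 at -2.40 ± 0.17 and the hypoxia-induced NDRG1 at -2.45 ± 0.17. The glial myelin gene PMP22 was lower, at -2.06 ± 0.09 (adjusted p = 9.44e-08).

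In limma, 4130 genes passed in IMR-32, 2161 higher and 1969 lower in the HOXC9 arrays, and of these 929 and 415 differed at least 2-fold. Among 10218 genes above the level threshold with a known neighbour order, 348 were called at 2-fold or more. Most 2-fold calls are thus of genes under that level or without a known neighbour order. The level is a mean over all arrays of both lines, so a gene bright in a single group can fall under it. ZNF671, at 10.94 in the IMR-32 HOXC9 arrays, has a mean of 4.52. Where a gene is near the lowest intensities in an arm, its fold depends on them. Of the 33 gene lists, 0 passed by camera (smallest adjusted p = 0.107, for genes of the unfolded protein and amino acid stress responses, 4 of 20 higher). Subtracting each gene's difference at 0 h, measured on 1 array against 1, left 30 genes past the threshold, of which 6 were among the 4130. Nothing in the labels says that the hours came from separate cultures, so these p-values may measure only the spread between arrays of different hours.

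In SK-N-AS, the same comparison between arrays labelled HOXC9 and GFP arrays found differences as well, although the HOXC9 probe went against the label. CLEC2B was higher by 9.30 ± 0.34 (adjusted p = 3.19e-08), from 2.31 ± 0.77 (SD, n = 5) in the GFP arrays to 11.61 ± 0.14 in the arrays labelled HOXC9. The transcription factor MEF2C was higher by 8.53 ± 0.47, the matrix metalloproteinase MMP3 by 7.57 ± 0.56, the scavenger receptor CD36 by 7.31 ± 0.40, the autophagy gene GABARAPL1 by 7.26 ± 0.26 and the activin antagonist FST by 7.03 ± 0.31. RNF217, TRPS1, PRUNE2 and SAMSN1 were higher by 6.18 to 6.85. FLI1 was lower here too, at -8.04 ± 0.22 (adjusted p = 4.38e-09), from 8.76 ± 0.14 in the GFP arrays to 0.72 ± 0.29. DLK1 stood at -7.32 ± 0.19, ID4, an inhibitor of basic helix-loop-helix factors, at -6.47 ± 0.15, and TIMP3, a metalloproteinase inhibitor, at -6.32 ± 0.20. ZNF439, DRC11, NPPC, WFIKKN2, HSD17B12 and KCNC1 were lower, at -6.24 to -5.42. Each of these 20 genes stayed past the threshold with the arrays of 6, 12 and 24 h left out.

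The SK-N-AS arrays labelled HOXC9 at 6, 12 and 24 h stood apart from those at 0, 48 and 96 h. Between these sets, array correlations ran from 0.964 to 0.975, against at least 0.996 within the former and 0.992 within the latter. The GFP arrays of SK-N-AS correlated at 0.972 to 0.994 over their 6 hours. Of 14471 probes above a log2 level of 9, 1170 differed at least 2-fold between these hours in the arrays labelled HOXC9, against 29 in the SK-N-AS GFP arrays and 31 in the IMR-32 HOXC9 arrays. Between HOXC9 and GFP labels, 2008 probes differed at least 2-fold at 6, 12 and 24 h and 583 at 0, 48 and 96 h, and between probes of the same gene these differences correlated at 0.499 and 0.811.

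**Figure D2:**
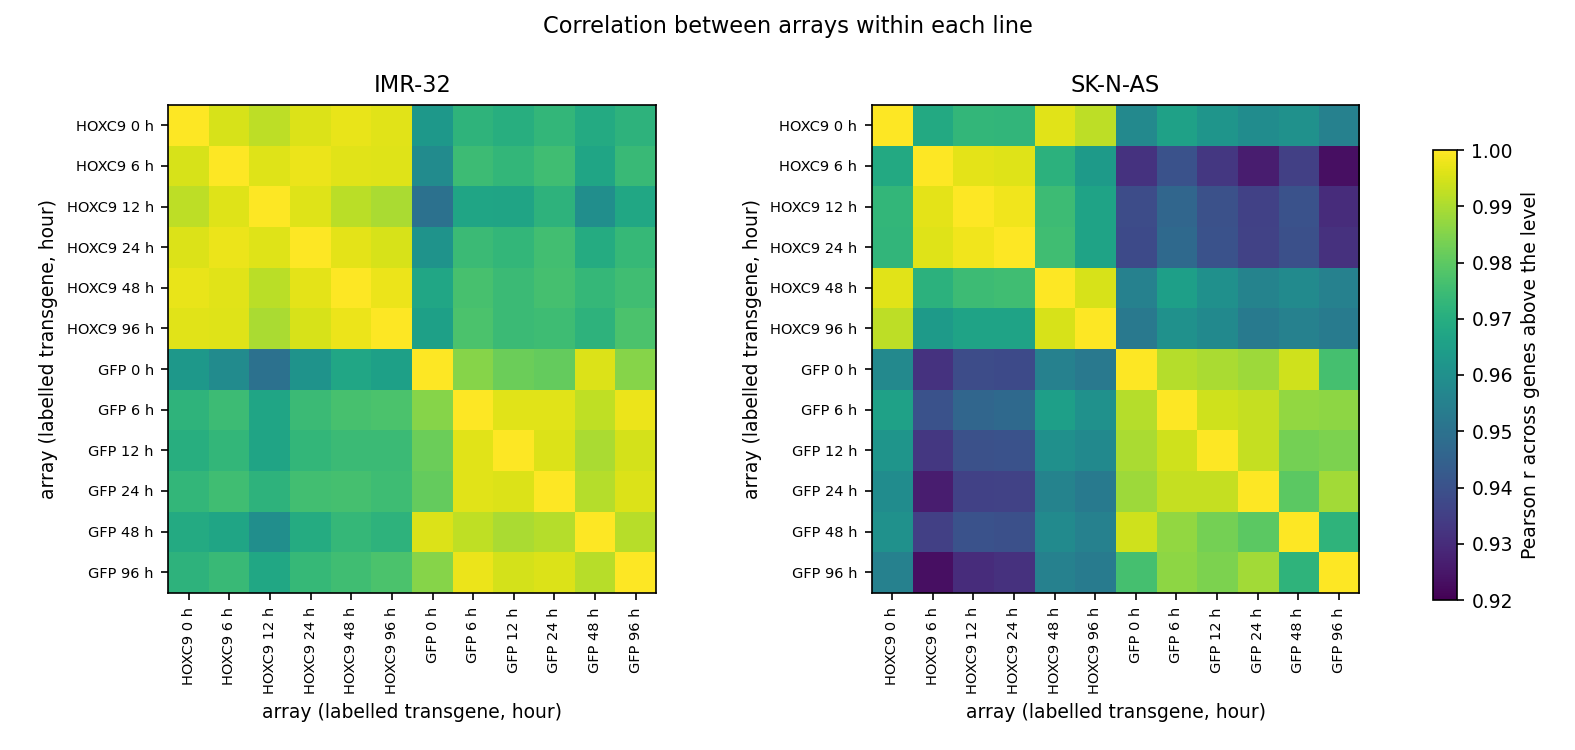
Pearson correlation across genes above the level threshold between arrays of the same line, with 1 panel per line, ordered by labelled transgene and hour on both axes. The colour gives r, and correlations between lines are not drawn. The SK-N-AS arrays labelled HOXC9 at 6, 12 and 24 h form a block whose correlations with the other hours of their group are 0.964 to 0.975.

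NF-kB target and inflammatory genes were higher together in the SK-N-AS arrays labelled HOXC9, against which the HOXC9 probe ran. Of 17 genes, 11 were higher and 0 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.000165; adjusted p = 0.0959 with an estimated correlation). BIRC3, which inhibits apoptosis, was higher by 6.17 ± 0.29, the cytokine IL1A by 3.16 ± 0.21, the adhesion molecule ICAM1 by 3.31 ± 0.40 and the NF-kB subunit RELB by 0.93 ± 0.07. At 48 and 96 h alone, away from the arrays that stood apart, these 4 differences were 6.08, 3.21, 3.14 and 0.91. Mesenchymal neuroblastoma genes were higher as well, 13 of 21 against 1 lower (14 and 1 adjusted over the list alone; camera adjusted p = 0.00244; adjusted p = 0.172 with an estimated correlation). CD44 was higher by 3.74 ± 0.26, the homeobox gene PRRX1 by 2.60 ± 0.30 and the receptor NOTCH2 by 1.36 ± 0.13, against 4.40, 2.70 and 1.65 at 48 and 96 h.

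Genes of the cell cycle were lower in the SK-N-AS arrays labelled HOXC9. Of 31 genes of G1/S and DNA replication, 19 were lower and 1 higher (20 and 1 adjusted over the list alone; camera adjusted p = 0.00498; adjusted p = 0.224 with an estimated correlation). CDC25A stood at -0.73 ± 0.07, the polymerase subunit POLA1 at -0.84 ± 0.14, cyclin E1, CCNE1, at -0.50 ± 0.09 and the licensing factor CDT1 at -0.79 ± 0.16. Of 28 genes of G2/M and mitosis, 13 were lower and 0 higher (14 and 0 adjusted over the list alone; camera adjusted p = 0.0234; adjusted p = 0.736 with an estimated correlation), such as AURKB at -0.99 ± 0.12 and PTTG1 at -0.58 ± 0.10. The G2/M list no longer passed with 6, 12 and 24 h left out (camera adjusted p = 0.0940) or without the 96 h arrays (camera adjusted p = 0.116). At 48 and 96 h CDC25A differed by -0.65, POLA1 by -0.42, CCNE1 by -0.27, AURKB by -0.90 and PTTG1 by -0.46. MKI67, at -0.32 ± 0.11 (adjusted p = 0.0325), no longer passed when the arrays of 6, 24, 48 or 96 h were left out (MKI67 in SK-N-AS HOXC9 vs GFP, adjusted p = 0.0537 to 0.0882). CCND1 was higher by 0.38 ± 0.08 and CDKN1A differed by -0.02 ± 0.17, which turned to 0.03 without 24 h and 0.15 without 96 h.

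Apoptosis genes moved both ways in SK-N-AS. Of 22 pro-apoptotic genes of the mitochondrial pathway, 4 were higher and 8 lower in the arrays labelled HOXC9, with the same counts adjusted over the list alone. Over all 17199 genes 3578 were called higher and 3680 lower, and the pro-apoptotic list did not pass (camera adjusted p = 0.502). HRK stood at -4.96 ± 0.20, the pore-forming BAK1 at -0.81 ± 0.08, PMAIP1 at -1.09 ± 0.17 and the caspase CASP6 at 0.74 ± 0.12. At 48 and 96 h PMAIP1 differed by -0.53, and HRK by -4.50. Among 12 anti-apoptotic genes, 4 were higher and 2 lower (4 and 2 adjusted over the list alone), with BCL2L10 at 1.93 ± 0.32, BCL2L1 at 0.42 ± 0.10 and BCL2 at -0.30 ± 0.10 (adjusted p = 0.0300). The BCL2 call ended without the arrays of 6, 12 or 96 h (adjusted p = 0.0566 to 0.0898). BBC3 was higher by 1.16 ± 0.27 on its brightest probe, but its other probes stood at -1.17 ± 0.28 and -0.60 ± 0.19. BAX was lower, at -0.26 ± 0.10 (adjusted p = 0.0495), while its other probe stood at 1.31 ± 0.35. Leaving out 6, 12 or 24 h ended the BAX call (adjusted p = 0.125 to 0.167). CASP9 differed by 0.14 ± 0.09 (adjusted p = 0.226). Of 28 p53 targets, 3 were higher and 12 lower (4 and 12 adjusted over the list alone), such as PHLDA3 at -1.27 ± 0.13 and GADD45A at -0.72 ± 0.08, but the list did not pass (camera adjusted p = 0.0668). Of 18 death receptor genes, 3 were higher and 4 lower, with the same counts adjusted over the list alone, such as CASP8 at -0.88 ± 0.25.

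Further genes of neuroblastoma identity and stress differed in SK-N-AS, but none of the lists named here passed (smallest camera adjusted p = 0.0664, for interferon-response genes). Of 22 noradrenergic genes, 8 were higher and 10 lower (9 and 10 adjusted over the list alone), with NPY at 3.29 ± 0.13, dopamine beta-hydroxylase, DBH, at -3.52 ± 0.22 and the noradrenaline transporter SLC6A2 at -2.39 ± 0.20. Of 28 neuronal differentiation genes, 10 were higher and 11 lower (11 and 13 adjusted over the list alone), with RTN1 at 3.98 ± 0.16 and SCG3 at -2.12 ± 0.13. Of 20 genes of the unfolded protein and amino acid stress responses, 11 were higher and 5 lower, with the same counts adjusted over the list alone. The serine synthesis genes PSAT1, at 2.28 ± 0.12, and PHGDH, at -2.03 ± 0.13, went opposite ways, and the chaperone HSPA5 stood at 1.61 ± 0.16. Of 18 interferon-response genes, 9 were higher and 2 lower (10 and 2 adjusted over the list alone), such as IFIT3 at 2.13 ± 0.24. Among other HOX genes, HOXD11 was higher by 1.90 ± 0.11 and HOXD10 by 1.69 ± 0.14, and HOXB3 stood at -3.10 ± 0.14. Of 8 endothelial markers, 5 were lower and 0 higher, with the same counts adjusted over the list alone, such as ENG at -1.45 ± 0.19, and the list did not pass (camera adjusted p = 0.0962). MYCN was higher by 0.80 ± 0.24 (adjusted p = 0.0204) on its brightest probe, but leaving out 6, 12 or 24 h ended the call (adjusted p = 0.0727 to 0.0806) and the difference at 48 and 96 h was 0.03. The other MYCN probes stood at -0.07, -0.31 and -0.20.

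In SK-N-AS HOXC9 vs GFP, limma called 7258 genes, 3578 higher and 3680 lower in the arrays labelled HOXC9, of which 1203 and 774 differed at least 2-fold, and 4 of the 33 lists passed by camera (0 with an estimated correlation). Among 10218 genes above the level threshold with a known neighbour order, 870 were called at 2-fold or more. With 6, 12 and 24 h left out, an alternative chosen after seeing the data, 3783 genes passed, of which 2983 were among the 7258. The order of the lines depends on whether they are fitted together. Fitted on each line's own arrays, 4441 genes passed here and 6575 in IMR-32 HOXC9 vs GFP, against 7258 and 4130. A line's log2 differences are the same in both fits, so only the estimated spread and its degrees of freedom differ. The joint fit gives each gene a single spread for both lines, and HOXC9 has an SE of 0.134 in each. How much the spread and the degrees of freedom each contribute was not tested. Subtracting the difference at 0 h left 42 genes, of which 17 were among the 7258, and 0 lists.

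**Figure D3:**
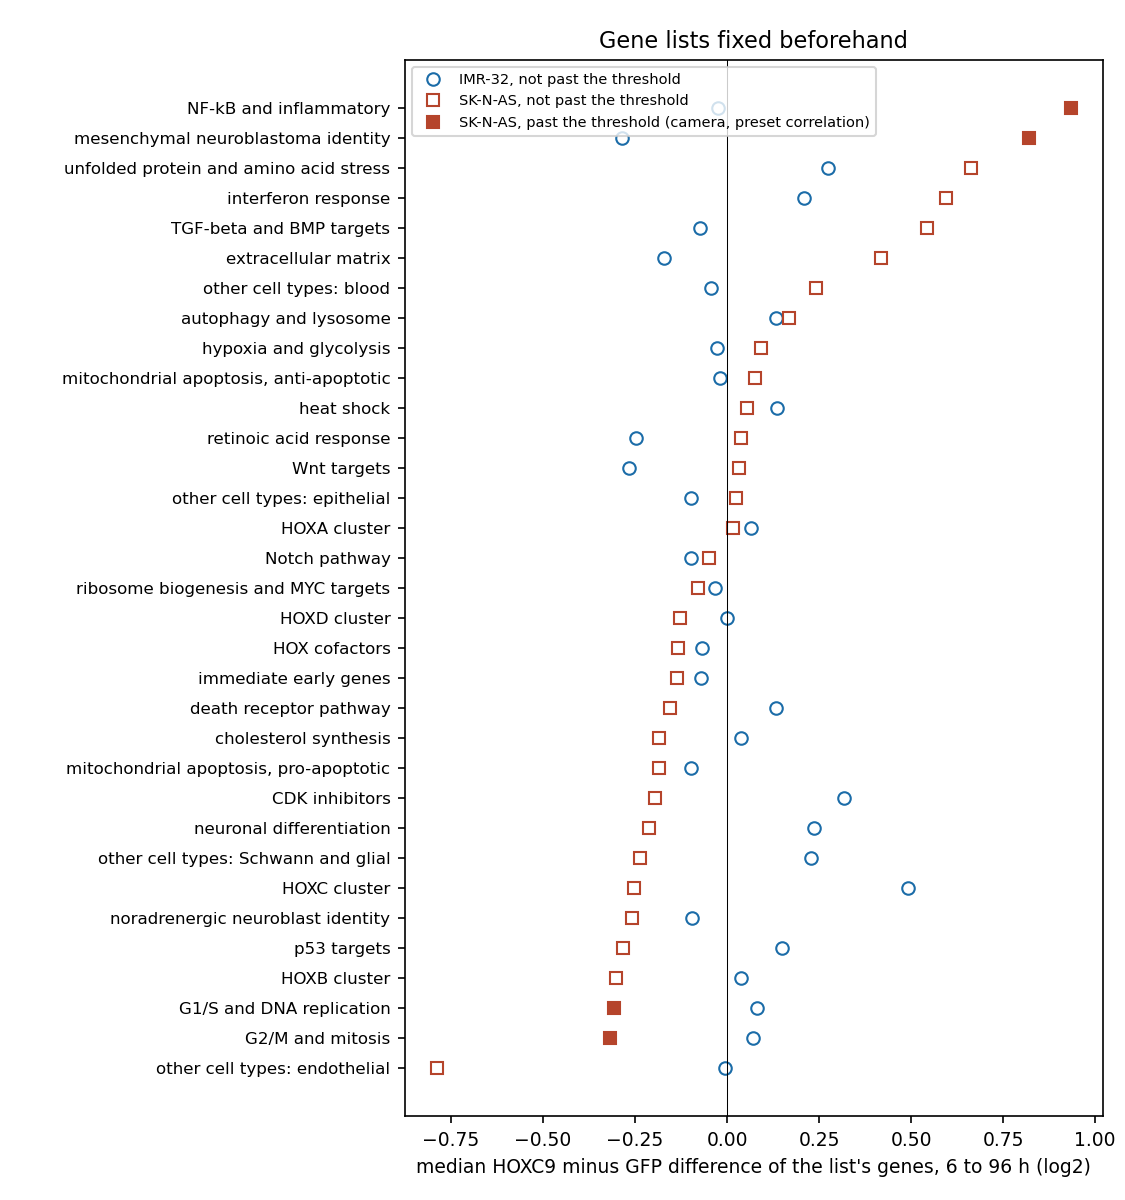
Median log2 difference, HOXC9 minus GFP at 6 to 96 h, of the measured members of the 33 gene lists (horizontal axis) in IMR-32 and SK-N-AS. In SK-N-AS the medians of the NF-kB and mesenchymal lists, 0.93 and 0.82, lie on the side of the arrays labelled HOXC9 and those of the cell cycle lists, -0.31 and -0.32, on the other.

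At 0 h the differences between HOXC9 and GFP arrays were already there. In IMR-32, EPHA5 differed at 0 h by 8.79, NEUROD1 by 6.38, RELN by 6.94 and FLI1 by -5.32. In SK-N-AS, CLEC2B differed by 9.05, MEF2C by 9.26, DLK1 by -6.36 and FLI1 by -6.17. Of the genes called at 2-fold or more, 1246 of 1344 in IMR-32 (92.7%) and 1903 of 1977 in SK-N-AS (96.3%) had the same sign at 0 h. The difference of a gene at 0 h was, in the median over these genes, 98.3% and 88.6% of its difference at 6 to 96 h. Across the 10319 genes above the level threshold, which are not independent replicates, the differences at 0 h and at 6 to 96 h correlated at r = 0.845 in IMR-32 and 0.770 in SK-N-AS. With 1 array per group at 0 h, no gene could be tested there alone.

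**Figure D4:**
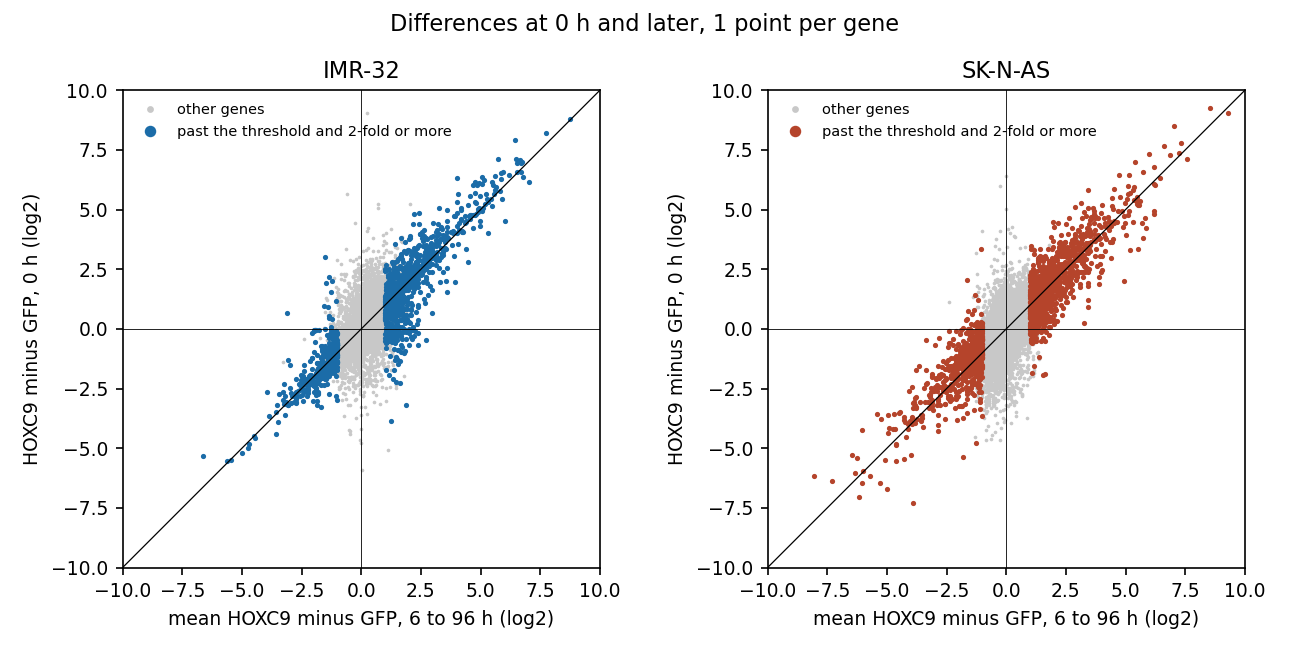
HOXC9 minus GFP log2 difference at 0 h (vertical axis) against that at 6 to 96 h (horizontal axis), 1 point per gene, in IMR-32 and SK-N-AS. Over all genes drawn r was 0.744 and 0.740, and over those above the level threshold 0.845 and 0.770. Over the latter, the slope of the 0 h difference on the later one was 1.068 in IMR-32 and 0.778 in SK-N-AS.

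Whether the difference between HOXC9 and GFP grew or shrank from 0 to 96 h was tested as a trend. In the SK-N-AS HOXC9 time trend, the smallest p among named genes belonged to the neuroendocrine gene RTN1, whose difference went from 2.38 at 0 h to 4.69 at 96 h, a slope of 0.50 ± 0.07 (adjusted p = 0.259). The neurosecretory VGF, at -0.46 ± 0.08, and the lipogenic desaturase SCD, at 0.24 ± 0.05, followed, with PITX1 at -0.50 ± 0.10, STC2 at -0.52 ± 0.11 and the kinase PIM1 at -0.28 ± 0.05, none past the threshold. ND6, CXXC4, DPY19L3 and GRB14 did not pass either. As a list, immediate early genes passed in SK-N-AS with a median slope of -0.24 over 16 genes (camera adjusted p = 1.01e-05; adjusted p = 0.141 with an estimated correlation), and heat shock genes with 0.13 over 11 genes (camera adjusted p = 0.00423; adjusted p = 0.803 with an estimated correlation). In both lists 0 members passed over all genes, and adjusted over the list alone 3 immediate early genes fell and 0 heat shock genes passed. In IMR-32, the smallest p in each direction among named genes belonged to KIAA1586, at -0.23 ± 0.06, and IFITM5, at 0.40 ± 0.12, and 0 lists passed (smallest camera adjusted p = 0.396). HOXC9 had a slope of -0.11 ± 0.08 in IMR-32 and 0.04 ± 0.08 in SK-N-AS, MYCN of 0.08 ± 0.15 and -0.22 ± 0.15, and BCL2 of 0.09 ± 0.07 and 0.04 ± 0.07. By limma 0 genes passed in either line (smallest adjusted p = 0.796 and 0.259), with 413 and 1205 genes at an unadjusted p under 0.05. Leaving out the 0 h arrays gave 2 genes in IMR-32 and 1554 in SK-N-AS, leaving out 48 h gave 84 in SK-N-AS, and leaving out the SK-N-AS arrays of 6, 12 and 24 h gave 50. Without 0 h, the SK-N-AS arrays labelled HOXC9 that stood apart, at 6, 12 and 24 h, all come before 48 and 96 h. The 1554 genes therefore cannot tell a trend from that split.

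With the labels as given, the effects differed between the lines. Among genes whose mean over these arrays lay above the level threshold, GAGE12F was lower in the IMR-32 HOXC9 arrays, at -5.62, and higher in the SK-N-AS arrays labelled HOXC9, at 2.29, a gap of 7.91 ± 0.25 (adjusted p = 2.43e-08). SHISA3, PRUNE2, ADORA2B and ENPP2 had gaps of 7.53, 6.48, 5.86 and 5.74 in the same direction. VEGFD was higher in IMR-32, at 6.71, and lower in SK-N-AS, at -4.08, a gap of -10.79 ± 0.39, and DLK1 stood at 3.31 and -7.32. NEUROD1, the chemokine receptor ACKR3 and IFI44 had gaps of -7.95, -7.64 and -7.29. Genes with a mean under that level had gaps larger than most of these, among them FST at 10.31, SAMSN1 at 10.14, CLEC2B at 9.25, MEF2C at 8.54, DRC11 at -10.66, ZNF439 at -10.16 and ERBB4 at -9.09. These were chosen after their values were seen. The HOXC9 gap was -4.65 ± 0.19, since the probe ran with the label in IMR-32 and against it in SK-N-AS. PMAIP1 had a gap of -1.33 ± 0.24 and BBC3, whose probes disagreed in SK-N-AS, of 1.63 ± 0.38. BCL2L1 had a gap of 0.48 ± 0.14 (adjusted p = 0.0198), which leaving out 6, 12 or 24 h brought to adjusted p = 0.0862 to 0.0919 (BCL2L1 in line by transgene interaction). On its brightest probe MYCN had a gap of 1.38 ± 0.33 (adjusted p = 0.00842), which with SK-N-AS 6, 12 and 24 h left out was 0.62 (adjusted p = 0.135). BCL2, BAX, CASP9, CDKN1A, CCND1 and MKI67 had no gap past the threshold (smallest adjusted p = 0.174, for BCL2; without 96 h 0.0232). With the arms of SK-N-AS turned, an alternative chosen after seeing the data, the gaps are others: GAGE12F in line by transgene interaction becomes 3.34, VEGFD in line by transgene interaction -2.63, DLK1 in line by transgene interaction 4.01 and HOXC9 in line by transgene interaction -3.51.

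The lists that passed in SK-N-AS also differed between the lines, again with the HOXC9 probe opposite. NF-kB genes had a larger difference in SK-N-AS in 9 of 17 and a smaller one in 1 (10 and 1 adjusted over the list alone; camera adjusted p = 0.00874), RELB by 1.41 ± 0.10 and IL1A by 3.23 ± 0.29. Mesenchymal genes had 14 and 6 of 21, with the same counts adjusted over the list alone (camera adjusted p = 0.0309), CD44 by 4.14 ± 0.37 and VIM by -1.31 ± 0.10. In the other direction stood 16 of 31 genes of G1/S and DNA replication (19 adjusted over the list alone; camera adjusted p = 0.00874), CDC25A by -0.95 ± 0.10, and 11 of 28 of G2/M and mitosis (11 adjusted over the list alone; camera adjusted p = 0.0144), CENPA by -1.06 ± 0.19. With an estimated correlation none passed (adjusted p = 0.318 for the NF-kB, mesenchymal and G1/S lists and adjusted p = 0.737 for G2/M). Without the arrays of 96 h 1 of these lists passed, and with SK-N-AS 6, 12 and 24 h left out 2 did, NF-kB and G1/S (camera adjusted p = 0.0209 for both). Limma called 6985 genes for the difference between lines, 3465 with the larger value in SK-N-AS and 3520 in IMR-32, and subtracting the 0 h difference left 40, of which 16 were among the 6985. With the arms of SK-N-AS turned, line by transgene interaction gave 5658 genes, of which 3220 were among the 6985, and 4 lists, of which 2 were among these: the NF-kB and mesenchymal lists, in the opposite direction (list NF-kB and inflammatory in line by transgene interaction, camera adjusted p = 0.00199; list mesenchymal neuroblastoma identity in line by transgene interaction, camera adjusted p = 0.0133).

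With the labels as given, genes called in both lines went opposite ways more often than the same way. With the arms of SK-N-AS turned, the counts for opposite ways and the same way would change places and the correlation its sign. Of the genes called higher in IMR-32, 687 were called lower in SK-N-AS, against 462.4 if the calls were independent (Fisher's exact test, two-sided, p = 1.22e-33), and 555 went the other way round, against 409.6 (p = 1.13e-16). Higher in both were 418, against 449.6 (Fisher's exact test, p = 0.0742), and lower in both 379, against 421.3 (Fisher's exact test, p = 0.0131). Fisher's test takes genes as independent, which they are not, so these p-values overstate the certainty. At 4-fold or more 33 genes went opposite ways and 28 the same way (exact binomial p = 0.609), and at 16-fold or more 3 and 6 (exact binomial p = 0.508). Over genes above the level threshold, which are not independent replicates, the effects of the lines correlated at r = -0.094. Among genes above the level threshold in their mean over all arrays, 29 were called higher and 14 lower in both lines at 2-fold or more, with the same sign at each of the 5 hours from 6 to 96 h. FLI1, lower in both, has a mean under that threshold and is not counted. Examples, chosen after their values were seen, are SLC12A7 at 3.27 ± 0.18 in IMR-32 and 3.54 ± 0.18 in SK-N-AS, the oxygen-sensing hydroxylase EGLN3 at 1.72 ± 0.16 and 1.98 ± 0.16, and NELL1 at -2.72 ± 0.21 and -2.82 ± 0.21.

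The GFP arrays alone gave the difference between the lines. MYCN was higher in IMR-32, at 15.22 ± 0.22 (SD, n = 6) against 8.83 ± 0.24 in SK-N-AS, a difference of -6.39 ± 0.16 (adjusted p = 1.24e-07). The collagen COL3A1 was higher in SK-N-AS by 12.51 ± 0.44, BRINP3 by 12.52 ± 0.37, the cancer-testis genes CTAG1A and MAGEA12 by 11.99 ± 0.13 and 11.45 ± 0.39, and ACKR3 by 11.82 ± 0.31. Higher in IMR-32 were GALNT14, at -12.82 ± 0.53, PGAP4, at -12.62 ± 0.26, and TAFA5, at -11.85 ± 0.17. Of 28 genes of neuronal differentiation, 20 were higher in IMR-32 and 3 in SK-N-AS (21 and 3 adjusted over the list alone; camera adjusted p = 1.79e-05; adjusted p = 0.469 with an estimated correlation), such as the neurofilament NEFM at -10.03 ± 0.13. Noradrenergic genes followed, with 13 of 22 higher in IMR-32 and 6 in SK-N-AS (14 and 6 adjusted over the list alone; camera adjusted p = 0.0337; adjusted p = 0.469 with an estimated correlation), with HAND1 at -6.64 ± 0.07, DDC at -7.83 ± 0.16 and RET at 6.11 ± 0.15. Extracellular matrix genes were higher in SK-N-AS in 19 of 23, and lower in 2 (19 and 2 adjusted over the list alone; camera adjusted p = 0.00189; adjusted p = 0.586 with an estimated correlation), such as COL1A1 at 9.15 ± 0.21.

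Interferon, immediate early and endothelial genes were higher in SK-N-AS. Interferon-response genes were higher in 13 of 18 and lower in 2 (15 and 2 adjusted over the list alone; camera adjusted p = 0.00691; adjusted p = 0.556 with an estimated correlation), with BST2 at 8.96 ± 0.29 and ISG15 at 5.40 ± 0.17. Immediate early genes were higher in 13 of 16 and lower in 2, with the same counts adjusted over the list alone (camera adjusted p = 0.0244; adjusted p = 0.800 with an estimated correlation), with MYC at 9.40 ± 0.13 and JUN at -2.44 ± 0.15. Endothelial markers were higher in 7 of 8 and lower in 0, with the same counts adjusted over the list alone (camera adjusted p = 0.0464; adjusted p = 0.556 with an estimated correlation), with TEK at 5.91 ± 0.13. The mesenchymal list did not pass, and VIM at 2.51 ± 0.07 and WWTR1 at 9.58 ± 0.36 went one way, S100A6 at -10.04 ± 0.32 and CD44 at -5.19 ± 0.21 the other. Of the apoptosis and cycle genes, CASP9 was higher in SK-N-AS by 1.58 ± 0.09 and CDKN1A by 0.74 ± 0.20, and BCL2 at -1.24 ± 0.12, CCND1 at -1.05 ± 0.08, BCL2L1 at -0.91 ± 0.08, MKI67 at -0.54 ± 0.11 and PMAIP1 at -0.45 ± 0.11 were higher in IMR-32. BAX did not differ past the threshold (adjusted p = 0.984), and BBC3, at -0.51 ± 0.18 (adjusted p = 0.0409), no longer passed without 0, 12, 48 or 96 h (adjusted p = 0.0614 to 0.106). In limma 11696 genes passed, 6595 higher in SK-N-AS and 5101 in IMR-32, with a median difference over all genes of 0.13.

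Time in culture changed no single gene past the threshold in the GFP arrays. The list of immediate early genes passed with a median slope of 0.08 (camera adjusted p = 2.92e-05; adjusted p = 0.631 with an estimated correlation), and that of heat shock genes with -0.06 (camera adjusted p = 0.000434; adjusted p = 0.656 with an estimated correlation). Neuronal differentiation genes, at -0.05, and genes of the unfolded protein and amino acid stress responses, at 0.02, passed as well (camera adjusted p = 0.0224 for both; adjusted p = 0.631 and adjusted p = 0.667 with an estimated correlation). In each of these lists 0 members passed, over all genes or adjusted over the list alone. Among named genes the smallest p in each direction belonged to GPR137C, at 0.14 ± 0.04, and TOB1, an antiproliferative gene, at -0.10 ± 0.03, and MKI67 had a slope of -0.09 ± 0.04. By limma 0 genes passed (smallest adjusted p = 0.986), with 502 at an unadjusted p under 0.05.

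Differences between HOXC9 and GFP arrays also ran along stretches of neighbouring genes, an analysis chosen after the data were seen. Gene order was taken from the GRCh38.p14 annotation, and medians were taken over 199 consecutive windows of up to 51 expressed genes. In SK-N-AS, 8 windows passed a limit of 0.298, 1 higher and 7 lower. The limit was an upper percentile of the largest absolute window median in each of 1000 shuffled orders. Of the lower windows, 6 were consecutive on chromosome 6, from DUSP22 to BMP5. The first of them, DUSP22 to ALDH5A1, had a median of -1.05, against -0.85 at 0 h and -0.93 at 48 and 96 h. The higher window ran from PTK2 to KIFC2, at 0.39. In IMR-32, 17 windows passed its limit of 0.182, 13 higher and 4 lower, the largest from CCDC28A to EZR, at 0.38. On chromosome 6 the higher windows ran without a break from TRERF1 to EZR, and those from H4C13 to PHF1 were lower. The other higher windows lay on chromosomes 12, 1 and 19, and the other lower ones on chromosome 17, from MIF4GD to QTGAL. In both lines each window past the limit had a median of the same sign at 0 h. Of 10218 expressed genes with a known neighbour order, the windows held 851 in IMR-32 and 390 in SK-N-AS. Of these, 316 and 280 were called, 294 and 252 of them in the window's direction. The windows were picked by the same values, so that direction is partly built in. Of the genes called at 2-fold or more, they held 34 of 348 in IMR-32 and 79 of 870 in SK-N-AS.

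**Figure D5:**
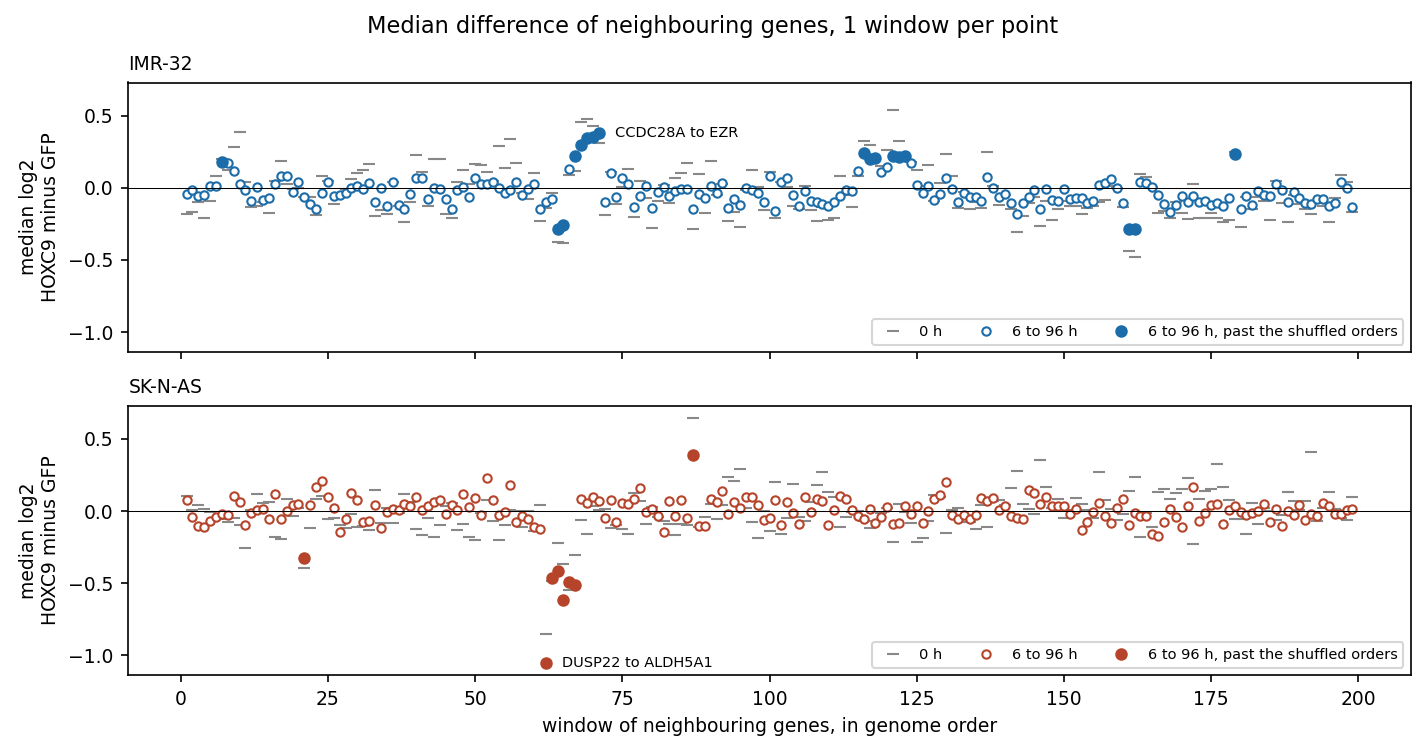
Median HOXC9 minus GFP log2 difference (vertical axis) of consecutive windows of up to 51 expressed genes in chromosome order (horizontal axis), in IMR-32 and SK-N-AS. The largest departures are the SK-N-AS windows from DUSP22 to BMP5, with medians down to -1.05.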

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

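The share of genes kept after subtracting neighbours and the counts of other splits were planned before the result was seen, and the tests between probes, within windows and between lines, and those on the arrays that stood apart and on the HOXC9 probe, were chosen only after it.

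The first pattern is that the HOXC9 minus GFP differences were there at 0 h. Differences between probes of the same gene at 0 h correlated at r = 0.854 in IMR-32 and 0.713 in SK-N-AS over 2307 genes, which argues against an offset of single probes. The lines' effects correlated at -0.094 with the labels as given. This argues against a response in the same direction, shared under these labels, as the bulk of the differences. A smaller shared response could go with such a correlation and stays open. Whether the transgene was raised in SK-N-AS is unknown. After the median of neighbouring genes was subtracted, 91.954% and 86.667% of the expressed genes called at 2-fold or more kept a 2-fold difference (320 of 348 and 754 of 870). The largest neighbour median was 0.419 in IMR-32 and -1.112 in SK-N-AS, so few of these genes could lose it. Most 2-fold differences thus exceed what neighbours share. Calls under 2-fold were left out, so the share cannot tell how far gains or losses of neighbouring genes account for those. Within the windows that passed the shuffled orders, genes were shifted at 0 h by a median of 0.327 and 0.468 in the window's direction, so gained or lost stretches may contribute there. Cultures that already differed before 0 h, and a transgene already active at 0 h, stay open as untested.

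The second pattern is that the SK-N-AS arrays labelled HOXC9 at 6, 12 and 24 h stood apart from 0, 48 and 96 h. The same contrast in the GFP arrays correlated with it at 0.015, which argues against a change with the hour that the arms share. The highest correlation of these arrays with an array of another group was 0.947, under the lowest within their own group, 0.964, which argues against arrays of another group under these labels, while over all hours arrays labelled HOXC9 reached 0.966 with GFP arrays. Between probes of the same gene the contrast correlated at only 0.282, and HOXC9 minus GFP at these hours at 0.499, against 0.811 at 0, 48 and 96 h, so a probe-level technical difference of these arrays may contribute. A change specific to the HOXC9 arm at these hours stays open, and the labels give no batch.

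The third pattern is that the HOXC9 probe was higher in the HOXC9 arrays of IMR-32 and lower in the arrays labelled HOXC9 of SK-N-AS. Labels exchanged between the arms of SK-N-AS cannot be told apart from right ones by the genes of 4-fold or more called in both lines, of which 28 went the same way and 33 opposite ways (exact binomial p = 0.609). At 2-fold or more 169 went the same way and 216 opposite ways (exact binomial p = 0.0189), which leans toward an exchange only if the lines share a response, and genes are not independent. In IMR-32, 4 of the 8 HOXC genes beside HOXC9 were higher too (Fisher's exact test, p = 0.0114). A difference of the cultures over the cluster may therefore add to the HOXC9 signal, although HOXC6 was lower at 0 h. Of these genes, HOXC5, HOXC6 and HOXC10 averaged no more than 3.89 in either arm, so the count leans on dim probes. Whether the probe detects the transgene is unknown.

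Other splits of the arrays into groups of the same sizes, 100 for each result with the real one, tested chance. For genes past the threshold, 1 split, the real one, reached the count in the following comparisons. In IMR-32 it gave 4130 (highest other 43) and in SK-N-AS 7258 (highest other 6515). For the difference between lines in the effect it gave 6985 (highest other 2), and for the GFP arrays between lines 11696 (highest other 3). These splits move single arrays without keeping hours balanced. For the difference between lines in the effect they move the HOXC9 and GFP arrays of an hour together. In the other comparisons, an hour with both arrays on one side adds nothing to the tested difference. Such splits therefore rest on fewer hours than the real one by construction. Where an arm is 1 culture, the splits also leave a chance difference between cultures open, so these counts do not exclude chance. The split with 6515 genes in SK-N-AS parts HOXC9 from GFP at 6, 12 and 24 h as the real one does, and has both arms of 48 h on one side and both of 96 h on the other. Chance cannot be excluded either for the trends at an unadjusted p under 0.05. There 61 splits reached the 413 genes of IMR-32 (highest other 3767) and 47 the 1205 of SK-N-AS (highest other 5153). Nor can chance be excluded for the lists. There 30 splits reached the 4 of SK-N-AS (highest other 7), 18 the 4 of the difference between lines (highest other 6) and 31 the 6 of the GFP arrays (highest other 10).

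Single arrays far from the other 5 of their group were found in 13 of 128 groups, where chance gives about 5%. The gap to the nearest array over the group's range was 0.973 for EPHA5 in IMR-32 GFP at 96 h (2.22 against 0.43 ± 0.02, SD) and 0.665 for MYCN in IMR-32 HOXC9 at 12 h (14.15 against 14.75). In the SK-N-AS GFP arrays at 48 h it was 0.631 for CLEC2B (0.96 against 2.55), 0.894 for RNF217 (1.63 against 0.65) and 0.779 for HSD17B12 (9.88 against 10.86). At 96 h in the same group it was 0.691 for KCNC1 (9.69 against 8.41), 0.645 for MYCN (8.39 against 8.92) and 0.723 for CASP9 (11.32 against 10.92). In the SK-N-AS arrays labelled HOXC9 it was 0.713 for FLI1 (2.42 against 0.72) and 0.677 for WFIKKN2 (5.02 against 3.67) at 0 h, 0.757 for BCL2L1 at 96 h (6.52 against 7.07) and 0.759 for CDKN1A at 6 h. The mean correlation of the IMR-32 GFP array at 0 h with its group gave 0.759 (0.986 against 0.993).

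By a test of the difference itself, 6985 genes had unequal effects in the lines with the labels as given, and 5658 with the arms of SK-N-AS turned (line by transgene interaction). With the labels as given, SK-N-AS minus IMR-32, the differences were 7.91 for GAGE12F, 7.53 for SHISA3, 6.48 for PRUNE2, 5.86 for ADORA2B, 5.74 for ENPP2, -10.79 for VEGFD, -10.63 for DLK1, -7.95 for NEUROD1, -7.64 for ACKR3, -7.29 for IFI44, -4.65 for HOXC9, 1.38 for MYCN, 0.48 for BCL2L1, 1.63 for BBC3 and -1.33 for PMAIP1.

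Of 16766 features without a gene symbol, which the comparisons of genes do not use, 3706 passed the threshold in IMR-32 (1256 higher, 2450 lower) and 4521 in SK-N-AS (1890 higher, 2631 lower).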

How the results depend on the processing

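Alternatives chosen after seeing the data were the offsets of 16 and 50 units, the scalings over tested genes alone, SK-N-AS without, or with only, chosen hours, and the arms of SK-N-AS turned. Scalings over all features moved nothing, since the arrays already share a distribution, and say nothing about stability. Outside the settings that leave out an hour, named genes kept their direction and side of the threshold in 558 cases in IMR-32, 611 in SK-N-AS, 419 for the difference between lines and 323 for the GFP arrays, and lost the threshold in 12, 50, 18 and 2. The kept cases take in those scalings over all features, which could not move a gene, so they overstate stability. Where no cause is given below, the cause was not tested.

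With fewer genes tested, the lowest 50% left out, counts fell to 1775 in IMR-32 HOXC9 vs GFP, 4623 in SK-N-AS HOXC9 vs GFP, 3726 for line by transgene interaction and 6510 for GFP line difference. With 24 to 96 h, fewer arrays, they were 1102, 2426 and 2472 for the first 3, and with array weights 7813 in IMR-32. Each line's own arrays gave 6575 and 4441. Leaving out an hour gave 2826 to 3576 genes in IMR-32, 5443 to 8026 in SK-N-AS, 4766 to 7217 for the interaction and 10823 to 11472 for GFP line difference, and lists from 3 to 6 in SK-N-AS and 1 to 4 for the interaction. SK-N-AS without 6, 12 and 24 h gave 3783 genes, and 2 lists for the interaction, as did 0, 48 and 96 h only.

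Trends depended on the hours: leaving out an hour gave 0 to 2 genes in IMR-32 HOXC9 time trend and 0 to 1554 in SK-N-AS HOXC9 time trend, hours as they are 1 and 9, and SK-N-AS without 6, 12 and 24 h 50. The 1554 came without 0 h, where a trend cannot be told from the split between 6, 12 and 24 h and the later hours. In SK-N-AS the mean of all probes gave 2 and the probe with the largest interquartile range 1. The GFP time trend gave 0 by limma throughout (502 at an unadjusted p under 0.05).

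Without the block for hour, which pairs the arrays, 4385 genes passed in IMR-32 HOXC9 vs GFP, 7324 in SK-N-AS HOXC9 vs GFP, 7130 for line by transgene interaction, 12083 for GFP line difference, 0 in IMR-32 HOXC9 time trend and 1 in SK-N-AS HOXC9 time trend.

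By camera with an estimated correlation 0 lists passed in any comparison. In IMR-32, 1 list passed under quantile normalization of tested genes, 1 under cyclic loess and 1 with the 0 h difference subtracted. The overlap between lines, same direction, rose from 797 to 1204 genes at an adjusted p under 0.1 and 1369 at an unadjusted p under 0.05, and overlap between lines, opposite direction, from 1242 to 2035 at the latter, since looser thresholds call more genes.

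Subtracting the 0 h difference, 1 array against 1, removes by construction what was there at 0 h, and its fit recovered 5.97% of simulated 2-fold changes in both lines. It left 30 genes in IMR-32, 42 in SK-N-AS and 40 for the interaction, with 0 lists in the latter pair. These reversed in IMR-32: EPHA5 -0.027, SLC24A3 -0.48, PPP1R17 -0.29, VEGFD -0.23, IFI44 -0.43, RELN -0.41, ZNF671 -0.069, TMEM204 0.044, FGF10 0.21, TES 0.11, SOX9 0.12, HOXC9 -0.078, BCL2 0.12, BCL2L1 0.052, BAX 0.17, BBC3 0.28, PMAIP1 -0.14 and CCND1 -0.052. In SK-N-AS these were MEF2C -0.74, CD36 -0.49, GABARAPL1 -0.12, FST -1.46, RNF217 -0.43, TRPS1 -1.06, SAMSN1 -0.59, DRC11 0.87, HSD17B12 0.46, BCL2 0.36, BBC3 -0.23, CCND1 -0.25, MKI67 0.29 and the list mesenchymal neuroblastoma identity in SK-N-AS HOXC9 vs GFP (adjusted p = 0.325). For the interaction they were GAGE12F -0.11, ENPP2 -0.54, NEUROD1 0.078, IFI44 0.38, HOXC9 0.048, BCL2L1 -0.050, BBC3 -0.51, CASP9 -0.10, CCND1 -0.20, MKI67 0.48, list G1/S and DNA replication in line by transgene interaction (adjusted p = 0.796), list G2/M and mitosis in line by transgene interaction (adjusted p = 0.305), list mesenchymal neuroblastoma identity in line by transgene interaction (adjusted p = 0.421) and list NF-kB and inflammatory in line by transgene interaction (adjusted p = 0.943).

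Choice of probe reversed others. With the probe of the largest interquartile range these were MYCN 0.022, CDKN1A -0.13 and CCND1 -0.056 in IMR-32, MYCN -0.068, BAX 1.31 and CDKN1A 0.46 in SK-N-AS, and MYCN -0.089, BAX 1.78 and CDKN1A 0.58 for the interaction. With the mean of probes they were BAX 0.52, BBC3 -0.20 and CDKN1A 0.22 in SK-N-AS, and BAX 0.78 and CDKN1A 0.12 for the interaction. Values near 0 changed sign elsewhere: CDKN1A in SK-N-AS with array weights (0.096), 0 to 96 h (0.056), 6, 12 and 24 h only (0.15) and an hour left out (-0.19 to 0.15), and BAX there without 6, 12 and 24 h (0.013) and with 0, 48 and 96 h only (0.005). For the interaction these were CASP9 under cyclic loess (-0.015), an hour left out (-0.010 to 0.13), without 6, 12 and 24 h (-0.013) and with 0, 48 and 96 h only (-0.030), BAX under the last settings (0.050 and 0.043), and MKI67 with array weights (0.008). In the GFP arrays BAX gave 0.082 with array weights and -0.041 to 0.038 with an hour left out.

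Turning the arms of SK-N-AS makes the test of a difference one of a sum, and left 5658 genes and 4 lists for line by transgene interaction. Reversed were SHISA3 in line by transgene interaction -4.83, PRUNE2 in line by transgene interaction -6.01, ADORA2B in line by transgene interaction -5.15, ENPP2 -0.30, DLK1 4.01, MYCN -0.22, BCL2L1 -0.35, BAX 0.30, BBC3 -0.69, PMAIP1 0.85, CASP9 -0.21, CCND1 -0.66, MKI67 0.52 and list G1/S and DNA replication in line by transgene interaction (adjusted p = 0.119), list G2/M and mitosis in line by transgene interaction (adjusted p = 0.389), list mesenchymal neuroblastoma identity in line by transgene interaction (adjusted p = 0.0133) and list NF-kB and inflammatory in line by transgene interaction (adjusted p = 0.00199).

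No detection flags were used, so signal over background is unknown, and folds against the lowest intensities depend on the offset.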

Other observations

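FLI1, a gene named by the rule in both lines, averaged 0.68 and 0.72 in the HOXC9 arrays of IMR-32 and the arrays labelled HOXC9 of SK-N-AS at 6 to 96 h, and 7.32 and 8.76 in their GFP arrays. Of the genes called in both lines at 8-fold or more, 9 went the same way and 12 opposite ways (exact binomial p = 0.664), and at 16-fold or more 6 and 3 (exact binomial p = 0.508), against 169 and 216 at 2-fold or more (exact binomial p = 0.0189). These thresholds were chosen after the values were seen.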
